A study of Caenorhabditis elegans with 4 samples.

How the data were processed

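The data come from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of CES-1 in Caenorhabditis elegans hermaphrodites at the L3 larval stage. CES-1 is a Snail-family zinc-finger transcription factor. Per the labels, the worms (strain OP174) carried a ces-1 transgene fused to EGFP and a FLAG tag in an unc-119 mutant background, together with an unc-119 rescue copy. Per the labels' protocols, synchronised worms were grown at 20 °C on E. coli HB101, crosslinked in 2% formaldehyde and sonicated, and the tagged protein was collected with an affinity-purified goat antibody against GFP. Part of the lysate was kept as input DNA. The 4 libraries are 2 ChIP replicates and 2 input replicates with the same numbers. Nothing in the labels states whether the replicates came from separate cultures, so the agreement between them may measure technical spread only.

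The authors deposited 3 lists of binding regions and a table that relates samples to files. Per the file headers, the regions were called with PeakSeq, a caller that scores ChIP enrichment against input DNA, and are given in WormBase WS220 coordinates. Comment lines in the deposited lists record that coordinates were lifted over to WS220. The earlier build, the aligner and the PeakSeq version are not given in the sources used here. Each region has a q-value given by the authors, and every deposited q-value lies below 0.01. Per the deposited sample table, 1 list was called on ChIP replicate 1, 1 list on ChIP replicate 2, and the combined list on the merged alignments of both replicates. The same table names 1 merged input alignment as the control of all 3 lists. Agreement between the replicate lists can therefore include structure of the shared input, and the deposited lists give no signal from which that part could be simulated. The table also gives the deposited read counts per sequencing run, as total reads and uniquely mapped reads of 36 bp. The non-uniquely mapped count is 0 for every run. There were 2 runs per ChIP replicate, and their counts were summed.

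From these files the following was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and bedtools 2.31.1. The q-value of each region was turned into a score, −log10(q), which serves only to describe, rank and filter regions. Regions of 2 lists were matched when they shared at least 1 bp, and bedtools gave the same counts. The number of matches was set against 1000 circular shifts of the replicate 2 list along each chromosome (two-sided permutation p, smallest possible value 0.002). Scores of matched regions were compared by Pearson and Spearman correlation across regions with 100000 permutations. Such correlations are across regions, which are not independent replicates. Chromosome lengths of WS220 were not used here. The end of the last deposited region on each chromosome took their place, 99.8 Mb in total. The density of regions on X was compared with that on the 5 autosomes, and the central 50% of each chromosome with its outer parts, each against 1000 random placements. For each placement the number of regions was drawn from a binomial distribution set by length. Random placement thus treats regions as independent and takes every base as mappable. Because regions lie close to each other, X against the pooled and the single autosomes, and central against outer parts of the pooled autosomes and of each chromosome, were also compared with whole 1 Mb windows as units, by 100000 permutations of windows. Permuting windows takes neighbouring windows as independent, although they can be alike. X is a single chromosome, so variation between chromosomes as such is not measured. Differences in mappability are not removed by windows, and the test of the central share of X against that of the autosomes was run over regions only. Shares carry 95% Wilson intervals, which cover counting error only. Density tests of X against single autosomes, and of central against outer parts of single chromosomes, were adjusted by the Benjamini-Hochberg method.

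The scripts were tested on simulated region lists. With 1000 regions of which 50% were shared, 50.2% were recovered. For 2713 regions, a set X-to-autosome density ratio of 1.4 gave 1.41 and a set central share of 60% gave 60.0%. Lists of 2713 regions without any difference gave a p below 0.05 in 7% of 100 draws in either density test. The simulated regions were placed independently, as the tests assume. This rate therefore does not cover regions that lie close to each other.

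The groups, the main tests, their settings and part of the alternatives were fixed before the data were examined. Not part of that plan were the tests with 1 Mb windows and those of X against single autosomes. The tests of the central share of X and the odds of being called within bands of combined score were also outside it. Alternatives covered the minimum overlap, list length, score thresholds, the lists used, the central boundaries and the null placement. The regions named are the 10 highest-scoring of the combined list and the 3 highest-scoring of each replicate without a match in the other. The 3 planned analyses that tie regions to genes or sequence were not run. These were the share of regions near gene starts, the binding of 28 gene lists, and the frequency of 10 E-box sequences. The only gene table at hand belongs to assembly WBcel235, and its coordinates were not combined with WS220. Regions are therefore named by position and no gene is assigned to any of them. The depth was 873921 and 1320404 uniquely mapped reads for ChIP replicates 1 and 2, and 1535649 and 907103 for input replicates 1 and 2.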

Results

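CES-1 binding was mapped in L3 larvae from 2 ChIP libraries and 2 input libraries. None of the libraries was a ChIP of worms without the tag, so enrichment unrelated to CES-1 was not measured. CES-1 regions are here the regions called against input. ChIP replicate 1 held 7426844 reads, of which 873921 were uniquely mapped (11.8%). ChIP replicate 2 held 11242035 reads, of which 1320404 were uniquely mapped (11.7%). Input replicates 1 and 2 held 2297457 and 1241087 reads, of which 66.8% and 73.1% were uniquely mapped. The caller returned 592 binding regions for replicate 1, 1195 for replicate 2 and 2713 for the merged reads of both. Replicate 2 thus had 1.51 times the uniquely mapped reads of replicate 1 and 2.02 times its regions. The combined regions had a median width of 222 bp. Together they covered 686075 bp, or 0.688% of the extent up to the last deposited region of each chromosome. The median width was 269 bp in replicate 1 and 230 bp in replicate 2. Regions narrower than 50 bp made up 253 of the combined list, 64 of replicate 2 and 3 of replicate 1.

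The highest-scoring CES-1 regions lay on chromosome V. The region at V, 9768660 to 9770149, had a combined score of 194 on the −log10(q) scale, with 87.1 in replicate 1 and 116 in replicate 2. Its neighbour at V, 9764902 to 9768416, ranked next with a combined score of 79.7, and with 20.9 and 36.7 in replicates 1 and 2. A gap of 243 bp separated these regions, and the pair spanned 5248 bp. The region in rank 3, at I, 4171991 to 4172627, had a combined score of 44.8 and replicate scores of 15.01 and 17.997. The 3 X regions that rank below it among the 10 highest scored higher than it in both replicates, with 15.7 or more in replicate 1 and 18.6 or more in replicate 2. All positions are WS220 coordinates, and no gene, exon or intron was assigned to them.

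The remaining regions among the 10 highest-scoring were spread over chromosomes X, I, III, IV and II. On X these were 16929399 to 16931880 with a combined score of 43.3, 14525557 to 14526142 with 40.4, and 11605504 to 11606582 with 35.6. On chromosome I the region from 6799475 to 6799909 scored 38.3. On chromosome III the region from 10435941 to 10436326 scored 35.9, on IV the region from 14032619 to 14034584 scored 35.9, and on II the region from 5543310 to 5544292 scored 31.5. Each of the 10 was called in both replicates, with scores of 11.8 or more in replicate 1 and 15.6 or more in replicate 2. Their widths ran from 386 bp to 3515 bp, against the median of 222 bp for the whole list.

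Whether the replicates found the same sites was asked first of the positions. Of the 592 replicate 1 regions, 448 overlapped a replicate 2 region (75.7%, 95% interval 72.1 to 79.0). Of the 1195 replicate 2 regions, 449 overlapped a replicate 1 region (37.6%, 34.9 to 40.4). The shares depend on list length, and with replicate 2 cut to its 592 highest-scoring regions they were 57.9% of replicate 1 and 58.1% of replicate 2. Circular shifts of the replicate 2 list gave a mean of 4.34 matched replicate 1 regions and at most 15, so the observed overlap exceeded every shift (permutation p = 0.002, the smallest that 1000 shifts can give). Agreement was highest for strong regions. Of the 50 highest-scoring replicate 1 regions, 50 had a match in replicate 2, as did 98 of the highest 100. Of the 50 highest-scoring replicate 2 regions, 49 had a match in replicate 1, as did 94 of the highest 100. Both lists were called against the same merged input, so part of the overlap beyond placement may come from the shared control.

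Regions found in a single replicate had lower median scores. The 746 replicate 2 regions without a match had a median score of 2.41, against 3.82 for the matched ones. The 144 replicate 1 regions without a match had a median score of 2.31, against 3.03. The strongest replicate 2 region without a match was at II, 11335827 to 11337065, with a score of 8.50 and a combined score of 12.97. It was followed by V, 15071067 to 15071709, with 7.16, and I, 9054873 to 9055194, with 6.66. The strongest unmatched replicate 1 regions were X, 5728971 to 5729728, with 4.78, IV, 11809537 to 11810105, with 4.46, and IV, 7619074 to 7619447, with 3.74. Each of these 6 regions overlapped a region of the combined list.

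The scores of shared regions were positively correlated between the replicates. Across 448 matched pairs they gave a Spearman rho of 0.58 and a Pearson r of 0.95 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 2 highest-scoring pairs, r was 0.83 and rho 0.57. Replicate 2, the deeper library, had the higher score in 315 of the 448 pairs (70.3%), with a median score difference of 0.71 (quartiles −0.093 and 2.02).

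**Figure D1:**
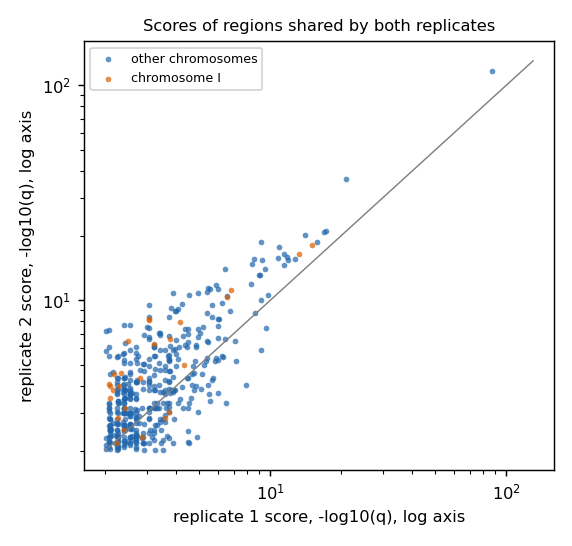
Scores, −log10(q), of the 448 regions shared by both replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis, both logarithmic; each point is a pair of overlapping regions and the line marks equal scores. The region at V, 9768660 to 9770149, stands apart at 87.1 and 116, and 315 of the 448 points lie above the line.

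The combined list was then set against the replicate lists. Of its 2713 regions, 442 were called in both replicates (16.3%, 14.95 to 17.7), 714 in replicate 2 alone (26.3%), 139 in replicate 1 alone (5.12%) and 1418 in neither (52.3%, 50.4 to 54.1). Conversely, 98.99% of replicate 1 regions and 97.2% of replicate 2 regions overlapped a combined region. The combined list was called on the merged reads of the same replicates, so this support is not independent evidence. Support rose with the combined score, as is partly built in by the shared reads. Of the 140 regions that scored above 10, 134 were called in both replicates and 0 in neither. Of the 465 regions that scored from 4 to 6, 86.5% were called in at least 1 replicate, and of the 714 that scored from 2 to 2.5, 7.70% were. Regions found in both replicates had a median score of 7.55 and a median width of 388.5 bp, against 2.53 and 175 bp for those found in neither.

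Support also differed by chromosome. Chromosome I held 400 combined regions (14.7%, 13.5 to 16.1), close to its 14.98% share of the extent. It held only 28 regions of replicate 1 (4.73%, 3.29 to 6.75) and 101 of replicate 2 (8.45%, 7.005 to 10.2). Among combined regions that scored from 4 to 6, replicate 1 called 2 of 69 on chromosome I and 169 of 396 elsewhere, and replicate 2 called 33 of 69 and 327 of 396. Regions were then compared within bands of combined score (2 to 2.5, 2.5 to 3, 3 to 4, 4 to 6, 6 to 10 and above 10). The Mantel-Haenszel odds of being called on chromosome I relative to the other chromosomes were 0.053 in replicate 1 (95% interval 0.025 to 0.11). In replicate 2 they were 0.18 (0.13 to 0.26). Scores can still differ between chromosomes within a band. For each other chromosome, compared with the rest except I, these odds ratios lay between 0.71 and 1.57. In replicate 2 the intervals excluded 1 for II (0.71, 0.54 to 0.93), X (0.74, 0.57 to 0.96) and IV (1.57, 1.19 to 2.07), and in replicate 1 for none of them. All these intervals take regions as independent and are not adjusted for the number of chromosomes compared.

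**Figure D2:**
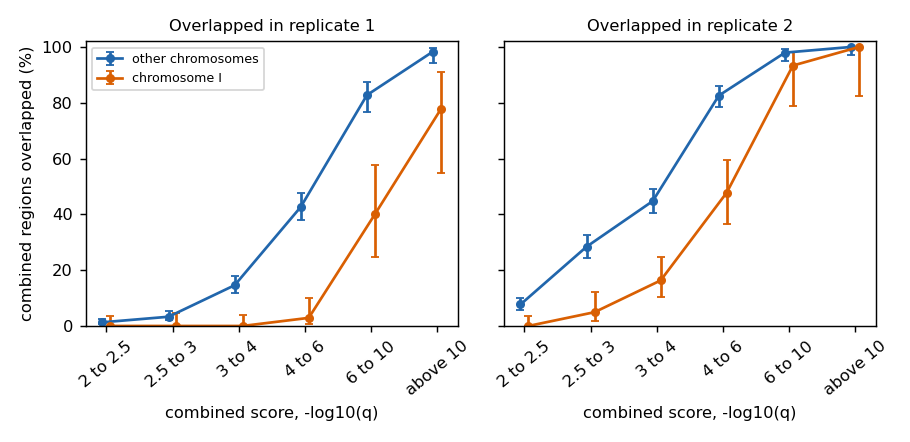
Percentage of combined regions overlapped by a region of replicate 1 (left) or replicate 2 (right), by combined score, for chromosome I and for the other chromosomes together; bars are 95% Wilson intervals. Among regions that scored from 4 to 6, replicate 2 covered 47.8% on chromosome I and 82.6% elsewhere.

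**Figure D3:**
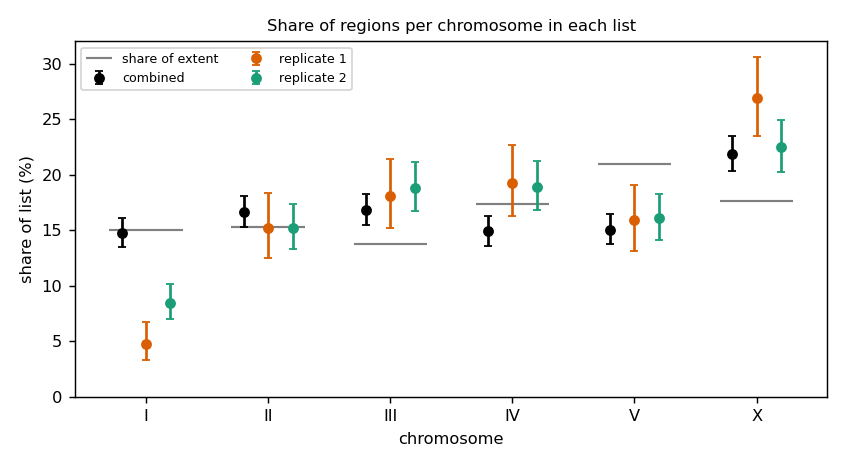
Share of the regions of each list (percent, with 95% Wilson intervals) on each chromosome. Grey lines give the chromosome's share of the extent up to the last deposited region of each chromosome. Chromosome I holds 14.7% of the combined list, 4.73% of replicate 1 and 8.45% of replicate 2.

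CES-1 regions were denser on X than on the pooled autosomes. X held 593 combined regions, or 33.6 per Mb, against 25.8 per Mb on the autosomes, a ratio of 1.30 (random placement gave 0.909 to 1.102 in 95% of draws, permutation p = 0.002, the smallest possible). X also held 43 of the 140 regions that scored above 10. With 1 Mb windows as units, X windows held 33.8 ± 7.21 regions (SD, n = 17) and autosomal windows 25.5 ± 11.5 (SD, n = 79; permutation p = 0.006). The autosomes differed widely. Chromosome III held 33.2 regions per Mb, II 29.6, I 26.8, IV 23.3 and V 19.5. X exceeded V 1.72-fold, IV 1.44-fold and I 1.26-fold (permutation test over regions, Benjamini-Hochberg adjusted p = 0.0033 each). With 1 Mb windows as units, the adjusted p was 0.0005 against V, 0.0013 against IV and 0.0358 against I. The ratio of X to II was 1.14, with an adjusted p of 0.04 in the random placement test over regions and of 0.405 in the permutation test with windows as units (29.7 ± 14.6 regions per window on II, SD, n = 15). Its ratio to III was 1.01 (random placement test, adjusted p = 0.871, and permutation test with windows, 0.603). In replicates 1 and 2 the ratio of X was 4.81 and 2.26 to I, of which these lists hold few regions, 1.53 and 1.28 to II, 1.16 and 0.93 to III, 1.37 and 1.17 to IV, and 2.004 and 1.66 to V. In the replicate lists the ratio of X to the autosomes was 1.71 in replicate 1 and 1.35 in replicate 2, and without chromosome I it was 1.50 and 1.24.

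On the autosomes, CES-1 regions concentrated in the chromosome centres. The central 50% of the autosomes held 1327 of 2120 regions (62.6%, 60.5 to 64.6), against 50% under random placement (permutation p = 0.002, the smallest possible). The central share was 69.6% on V, 64.4% on II, 62.0% on I, 60.1% on IV and 57.2% on III, each above placement (permutation test, adjusted p = 0.0048 or lower). With 1 Mb windows of each autosome as units, the adjusted p ranged from 0.0045 on V to 0.0452 on II (permutation test). Central autosomal windows of 1 Mb held 31.8 ± 9.71 regions (SD, n = 41) and outer windows 18.7 ± 9.15 (SD, n = 38; permutation p = 1e-05). X had no such concentration that the test could detect, with a central share of 52.1% (48.1 to 56.1; permutation test, adjusted p = 0.322). The central share was 10.5 percentage points lower on X than on the autosomes, a difference that Fisher's exact test over regions gave as p = 5e-06 (two-sided). That test takes regions as independent, although they lie close to each other. It was not repeated with windows, so its p may be too small. The concentration on the autosomes held in each replicate, with 62.4% of 433 regions in replicate 1 and 60.9% of 926 in replicate 2. Neither the placement nor the windows account for mappability. A difference in mappability between central and outer parts was therefore not separated from a difference in binding.

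**Figure D4:**
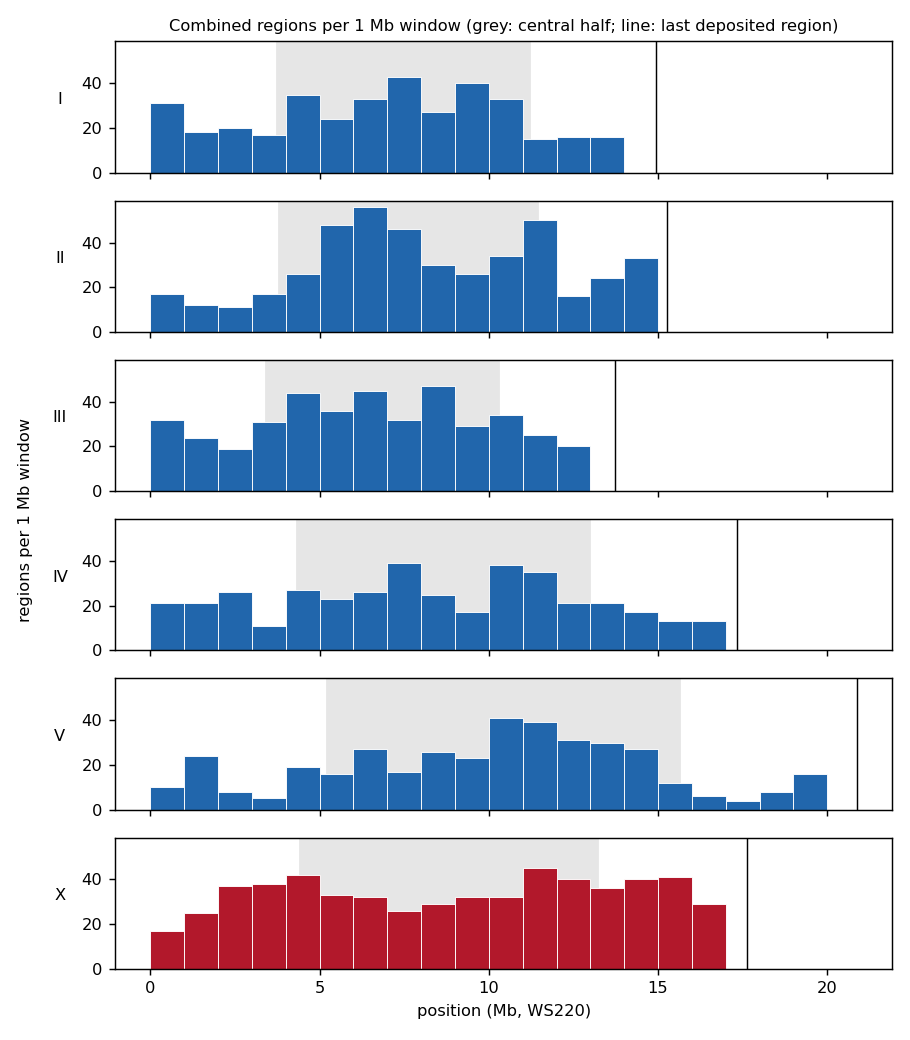
Combined regions per whole 1 Mb window (vertical axis) along each chromosome in WS220 coordinates (horizontal axis, Mb); grey marks the central 50% of the extent and the black line the end of the last region, and the incomplete last window is left out. Autosomal windows average 31.8 regions in the centre and 18.7 outside it, and the 17 windows of X range from 17 to 45.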

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

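Alternatives with chromosome I or another chromosome left out, with the 2 highest pairs left out, with 1 Mb windows, with X alone or with narrow regions removed, and support by a single replicate, were chosen after seeing the data. Of 36 alternative settings for the main results, with both overlap shares of a setting counted as 1, 29 kept the direction and the side of the threshold, among them every one tried for the overlap of the replicates, their score agreement and the density of X against the pooled autosomes. For single chromosomes, 1 Mb windows kept the side of the threshold in 10 of 11 comparisons. The ratio of X to II, 1.14, lost it (permutation test, adjusted p = 0.405). The overlap of replicate 1 ranged from 57.9% (equal list lengths) to 78.7% (higher-scoring part of each list), and that of replicate 2 from 32.3% (50% reciprocal overlap) to 58.1% (equal list lengths). The share of combined regions called in at least 1 replicate, 47.7%, moved beyond its interval in all 6 alternatives. It was 42.7% with 50% reciprocal overlap, 77.3% in the higher-scoring part of the combined list, 51.6% without chromosome I and 51.5% for regions of at least 50 bp. Support by 1 replicate, whether or not the other also called the region, ranged from 21.4% (replicate 1) to 42.6% (replicate 2). Support by 1 replicate is part of support by either and is lower by construction, and the rise without chromosome I follows from the low support of its regions (49.3% against 92.9% elsewhere at combined scores from 4 to 6). The fall with 50% reciprocal overlap follows from the stricter rule, and the rise in the higher-scoring part goes with the support by score, from 7.70% at combined scores of 2 to 2.5 to 100% above 10. The rise for regions of at least 50 bp was not examined further. The central share of 62.6% on the autosomes fell to 52.1% (permutation p = 0.322) when X took their place, which changes the chromosomes by construction. The ratio of X to autosomes ranged from 1.35 (replicate 2 alone) to 1.71 (replicate 1 alone) when a replicate was left out, and was 1.76 for combined regions found in both replicates, a list that lacks much of chromosome I. The alternatives for gene starts, gene lists and E-box sequences were not run, because no genome or annotation of the files' build was used here. No paired analysis was possible because the deposited lists hold no value for a single input library and no test across libraries was fitted. Whether the depth of 873921 uniquely mapped reads in replicate 1 limits its calls of weak regions was not tested at equal depth.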

Other observations

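The density of CES-1 regions on X was set against that of autosome centres, a comparison chosen after the densities were seen. The 17 whole 1 Mb windows of X held on average 1.94 regions more than the 41 central autosomal windows (95% bootstrap interval −2.52 to 6.29, permutation p = 0.467), so a difference of up to 6.29 regions per window is not excluded. CES-1 regions also lay close to each other. Of the 2713 combined regions, 285 had another region's centre within 1000 bp (10.5%), against a mean of 200 when each region was moved by up to 50 kb (permutation p = 0.002, the smallest possible). With regions of at least 50 bp the count was 239 against 164. The densest 100 kb windows, picked after their counts were seen, held 13 regions each at II, 7900001 to 8000000, V, 10800001 to 10900000, and X, 12600001 to 12700000, of which 3, 6 and 7 were called in a replicate. Random placement without regard to the broad density gave a densest window of 9.9 regions on average and 14 at most (permutation p = 0.026). Placement within each 1 Mb window keeps the broad density. It gave 10.9 on average and 16 at most (permutation p = 0.144), so no excess beyond the density of the surrounding 1 Mb was detected. Moves by up to 50 kb gave 12.5 on average (permutation p = 0.937). They cannot decide this, because such moves largely keep crowding on the scale of a 100 kb window.

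All tests of explanations in this part were chosen after the result was seen. The first pattern is the low chromosome I share of both replicate lists, 4.73% and 8.45%, against 14.7% in the combined list; all lists come from the same libraries, so no biological explanation was tested. Lower depth of single replicates would act on all chromosomes. It is argued against as the whole cause by the odds of recovery on chromosome I within bands of combined score. These were 0.18 (0.13 to 0.26) in replicate 2 and lower in replicate 1. These odds mean that a smaller share of chromosome I regions passed the calling threshold in the replicates than of others in the same score band. Above a combined score of 10, replicate 1 called 14 of 18 regions on I and 120 of 122 elsewhere, while replicate 2 called all 140. Whether replicate scores on chromosome I are lower chromosome-wide, also among strong regions, stays open. The p-value of the score difference depended on whether the 2 highest regions were kept. Among the 140 regions of combined score above 10, replicate scores on I were set against those of other chromosomes, within blocks of 10 regions of neighbouring combined rank. The difference, I minus others, was −3.98 in replicate 2 (permutation p = 0.199). In replicate 1 it was −3.12 with uncalled regions, 4 on I and 2 elsewhere, set to the threshold score of 2 (permutation p = 0.198). Among called regions alone it was −3.45 (permutation p = 0.2). Without the 2 highest regions, on V, the difference was −2.24 in replicate 2 (permutation p = 1e-05, the smallest possible) and −1.89 in replicate 1, uncalled regions included (permutation p = 3e-05), but this exclusion was chosen after the first values were seen. Whether the replicate calls score chromosome I too low or the combined call scores it too high stays open, as does the step responsible, for example a scaling of input made per chromosome.

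The second pattern is the longer list of replicate 2, 2.02 times that of replicate 1. Lower depth in replicate 1 and stronger enrichment in replicate 2 cannot be told apart here. The replicate 2 regions absent from replicate 1 were its weaker ones (median score difference −1.41), but so were the replicate 1 regions absent from the deeper replicate 2 (−0.72). These differences decide nothing, because the median scores of unmatched regions, 2.41 in replicate 2 and 2.31 in replicate 1, lie near the calling threshold. Replicate 2 had 1.34 times as many regions per uniquely mapped read, at unequal depth.

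The uniquely mapped share was 10.9% to 12.4% in the 4 ChIP runs and 66.8% and 73.1% in the input libraries, with 0 non-uniquely mapped reads listed for any of them.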
